A study of Homo sapiens with 11 samples.

How the data were processed

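Chromatin from THP1, an established human monocytic leukaemia cell line, had been crosslinked with 1% formaldehyde, sheared and precipitated with 11 antibodies, per the labels' protocols. Of the antibodies, 3 recognise histone marks (H3K4Me3, H3K9Me2 and H3K27Me3) and the other 8 recognise chromatin proteins. Each antibody had 1 hybridisation to a promoter array with 2 channels, called an array here. By the slide names, H3K4Me3 and JHDM2A had the same slide, as did H3K9Me2 and JHDM1A, and H3K27Me3 and JHDM3A. The track names of JARIDIA, LSD1, JHDM1A, JHDM2A, JHDM3A and SIN3A carry a mark of re-use. The precipitate was read at 635 nm and a control at 532 nm, as the labels and the file headers give them. The labels describe the control in different ways, as DNA from a control immunoglobulin and as a precipitation without antibody that served as input, so the kind of control stays open here. The label JARIDIA is kept as written and is read as JARID1A.

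Per the file headers, each scanner file holds the deposited intensity of every probe in 1 channel on a linear scale. NimbleScan 2.4.27 is named as the extraction software in those headers that give one. Background subtraction and within-array normalisation are not given in the sources used here. The authors also deposited a track of log2 ratios per array, and a value table that held the same log2 values as the tracks (largest difference 0). Set against the scanner intensities, the track of 10 antibodies was the log2 ratio of the 635 nm over the 532 nm channel (Pearson correlation 1.0 over probes) shifted to a centre near 0, with column medians between -0.01 and 0.04. The BRG1 track came from another slide than the BRG1 scanner files (correlation 0.43), so its ratios were computed from the scanner files and the track was used only as an alternative. Coordinates are those of the array design (hg18).

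From the intensities, the log2 ratio of precipitate over control was computed for each of 386230 promoter probes and each array was centred on its median, with no loess or quantile step. The array also carries 3077 random-sequence probes, which served as a measure of background. A region is a tiled promoter of the array design. The array holds 18028 regions, 88.7% of them 2700 bp long, with a median of 22 probes spaced 100 bp apart. A running mean over 5 consecutive probes no more than 500 bp apart was taken. A region was called enriched where its highest running mean reached the smallest level, on a grid of 0.05 log2, at which regions with a running mean as far below 0 numbered at most 5% of those above. This left 17973 regions tested. The region value is the mean log2 ratio over the probes of a region. The tracks record how many genome matches each probe has, and 24464 probes (6.3%) have more than 1.

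No antibody has a replicate array, so no p-value is given and no difference between antibodies was tested. Correlations between antibodies are across regions, which are not independent replicates. Shared regions are set against the number that independent lists would share. The number of arrays limits the precision of every value. The SD given with a region is the spread of its probes on 1 array, and not an error between replicates.

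The rule for named regions was the 10 highest region values among the enriched regions of each histone mark, the 5 highest for each protein, and the 5 highest sums among regions enriched for both H3K4Me3 and H3K27Me3. It was fixed before the data were examined. It was meant for genes, but the files pair no region with a gene, and the gene table at hand belongs to another genome build, so regions are named by position and the planned comparisons of gene lists were not run. Transcription start sites and strands of the hg18 annotation were not used here. Chromosome Y regions are not named.

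Alternatives were centring on the mode, normexp background correction with an offset of 50 (limma 3.58.1 in R 4.3.3), the authors' tracks, the mean control of all arrays as control, removal of each array's lowess trend of the ratio on control signal, windows of 3 and 9 probes, a lower tail of 1%, leaving out the 10% dimmest probes, the 1000 highest regions of each antibody, the highest running mean as region value and the median over probes. Leaving out probes with more than 1 match, and for runs leaving out regions made mostly of such probes, was added after the data were seen. Runs of neighbouring enriched regions allow gaps of up to 200 kb and were set against 1000 shuffles of the calls within chromosomes. The other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

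The calling step was tested on simulated data with the real probe layout, each array's SD and a set correlation of 0.5 between neighbouring probes. Of the 17973 regions 200 per size carried a raised run of 8 probes. At 2.0 log2, the share recovered was 39.0% at the SD of the H3K4Me3 array, 99.0% at that of H3K9Me2, 97.5% at that of H3K27Me3, 94.0% at that of SNF2H and 96.5% at that of BRG1. At the SD of the JARIDIA array it was 9.0% at 2.0 log2 and 46.0% at 3.0 log2. The level to reach was found anew in the simulated data, and the SD of an array holds its real signal as well as noise. These shares are therefore not the sensitivity at the levels used on the real arrays, such as 0.6 log2 for H3K4Me3. The simulated arrays without raised runs gave between 0 and 4 calls each, in symmetric noise that the lower-tail rule presumes. In those with raised runs, between 4 and 36 regions without one were called, 25 at the SD of SNF2H and 32 at that of BRG1.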

Results

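The series measured where 3 histone marks and 8 chromatin proteins lie over the promoters of THP1 cells, a human monocytic leukaemia line, without treatment. H3K4Me3 is the mark of active promoters, H3K27Me3 the mark laid down by Polycomb complexes, and H3K9Me2 a mark of silent chromatin. JARIDIA and LSD1 (histone H3 lysine 4 demethylases), JHDM1A, JHDM2A and JHDM3A (demethylases of the Jumonji family), SIN3A (a corepressor scaffold), and SNF2H and BRG1 (ATPases of nucleosome remodelling complexes) are the proteins. Each antibody had 1 array and no replicate. The median intensity of promoter probes was between 182 and 786 in the precipitate channel and between 337 and 607 in the control channel. On the 3 histone arrays the control lay near background. There, 11.3% to 12.4% of promoter probes exceeded the 95th percentile of the random-sequence probes in the control channel, against 44.6% to 54.5% on the protein arrays. The SD of the log2 ratio over probes ran from 0.57 for H3K9Me2 to 1.25 for JARIDIA.

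The first question was how many promoters were called enriched for each mark or protein. With each array's own control and median centring, H3K4Me3 had the highest count. It was enriched in 9789 of 17973 regions (54.5%), with 231 regions as far below 0. H3K9Me2 was enriched in 2490 regions (13.9%) and H3K27Me3 in 2348 (13.1%), with 123 and 44 lower-tail regions. Among the proteins, JHDM1A had 2846 enriched regions, LSD1 had 2527, JHDM3A had 1672, SIN3A had 823, JARIDIA had 419 and JHDM2A had 329. SNF2H had 5 and BRG1 had 1. The level that a region had to reach differed between arrays. It was 0.6 log2 for H3K4Me3, 0.8 for H3K9Me2 and 0.9 for H3K27Me3, and ran from 1.55 for JHDM1A to 3.1 for JARIDIA among the proteins. The counts are therefore not on 1 scale of occupancy. The counts depend on how the control signal enters, on the centring and on the calling rule. A lower tail of 1% gave 14 regions for JHDM3A, 950 for JHDM1A and 838 for LSD1, but 9609 for H3K4Me3. With the mean control of all arrays, LSD1 had 6300, above the 6127 of H3K4Me3, while H3K9Me2 had 4, JARIDIA had 3609, SIN3A had 4559 and JHDM2A had 2310. With centring on the mode, LSD1 had 17602, JHDM1A had 15159 and H3K9Me2 had 12278, all above the 11440 of H3K4Me3. In that setting SIN3A had 87, and JARIDIA, SNF2H and BRG1 had 0. After the trend of each array's ratio on control signal was removed, JARIDIA had 276, JHDM3A 285, LSD1 45, SIN3A 38 and JHDM2A 20, and JHDM1A, SNF2H and BRG1 had 0, whereas H3K4Me3 had 9944, H3K9Me2 had 2776 and H3K27Me3 had 3634. With normexp background correction no protein had more than 26.

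**Figure D1:**
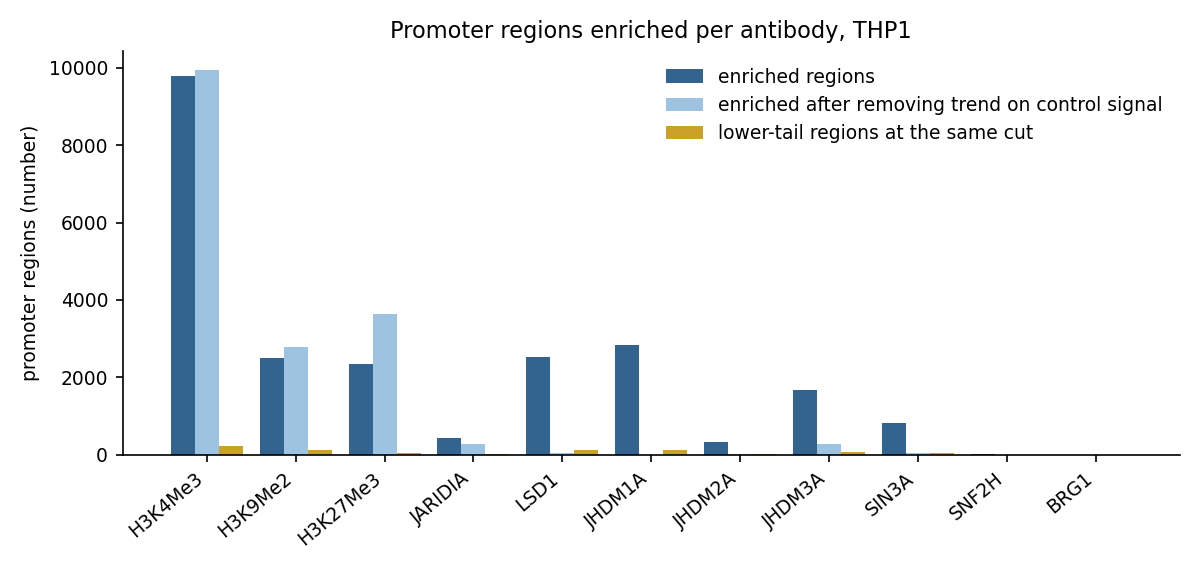
Bars give the number of promoter regions (vertical axis) enriched for each of the 11 antibodies (horizontal axis), the number after removing the trend of the ratio on control signal, and the number of regions as far below 0 as the enriched ones are above it; each antibody has 1 array. H3K4Me3 stands at 9789 and 9944 regions, while LSD1 goes from 2527 to 45.

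The second question was how the 3 marks combine at promoters. H3K4Me3 alone marked 8194 regions (45.6%). H3K27Me3 alone marked 1025 (5.7%), H3K9Me2 alone 1049 (5.8%), and no mark reached its level in 5619 (31.3%). H3K4Me3 shared fewer regions with the silent marks than independent lists would share. It shared 832 with H3K27Me3 against 1278.8 (ratio 0.65) and 950 with H3K9Me2 against 1356.2 (ratio 0.70). Among the 1000 highest regions of each antibody, the ratio for H3K4Me3 with H3K9Me2 was 1.46. With centring on the mode it was 0.96, against 0.70 for H3K4Me3 with H3K27Me3. With the mean control of all arrays H3K9Me2 had 4 regions, too few for a ratio. H3K9Me2 and H3K27Me3 shared 678 regions against 325.3 (ratio 2.08), and 187 regions carried all 3 marks. That ratio was 1.30 with centring on the mode and 3.81 among the 1000 highest regions.

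The highest H3K4Me3 values were on chromosomes 1, 6, 8 and 11 (hg18). The region at chromosome 1, 40744819 to 40747519, had the highest mean log2 ratio, 2.87 ± 1.06 (SD over 14 probes). The region at chromosome 1, 245645773 to 245648473, followed with 2.63 ± 1.59 (SD over 18 probes), then chromosome 6, 43590568 to 43594880, with 2.58, chromosome 8, 109329628 to 109332328, with 2.57, and chromosome 8, 86204515 to 86207215, with 2.56. The other 5 lay between 2.45 and 2.55. They were at chromosome 1, 43625942 to 43630270, chromosome 1, 40767619 to 40770319, chromosome 1, 229538104 to 229542401, chromosome 1, 40121264 to 40123964, and chromosome 11, 62377893 to 62380593. Of these 10 regions 3, the first among them, lie in a stretch of chromosome 1 from 39929176 to 41102805 where the control signal itself was raised. Its bounds are where the running median of control signal over 9 regions fell midway from its peak to the median of all regions. The signal stayed raised beyond them, with a running median of 0.67 (log2) still at 43943604, against 0.14 over all regions. The named region at 43625942, outside the stretch, had a control signal of 1.52. Over the 21 regions of this stretch the mean control of the 8 protein arrays was 2.5 times that of the median region, and the median H3K4Me3 value was 1.56 against 0.21 over all regions (1.30 with normexp).

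**Figure D2:**
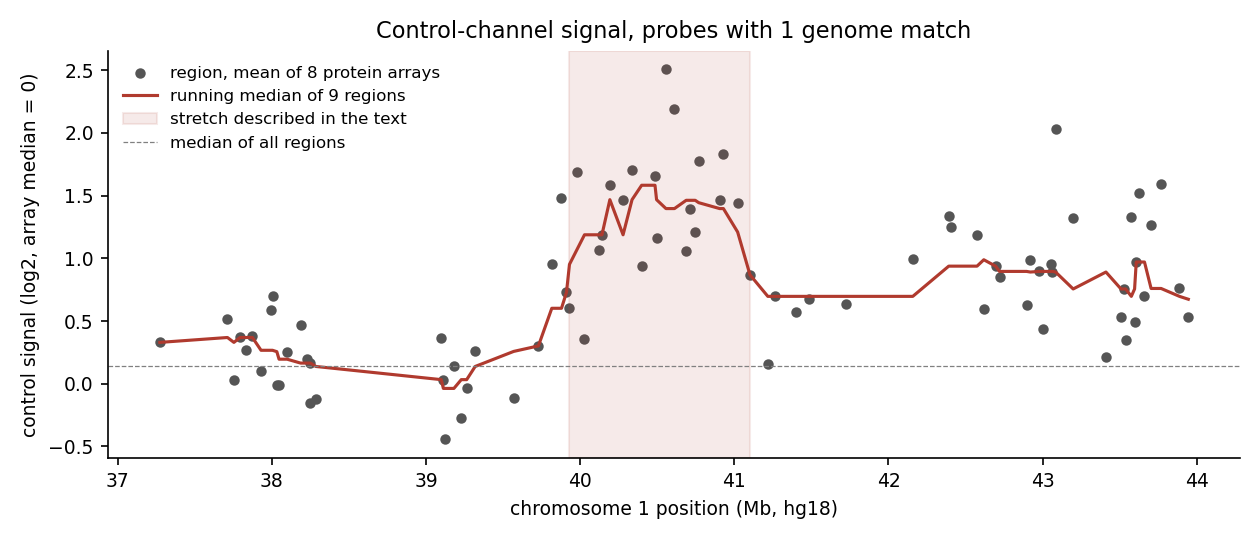
Points give the control-channel signal of each region (vertical axis, log2 with the array median at 0, mean of the 8 protein arrays, probes with 1 genome match) along chromosome 1 (horizontal axis, Mb in hg18), and the line is the running median of 9 regions. The shaded stretch holds 21 regions, and the running median reaches 1.58 there against a median of 0.14 over all regions.

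The highest H3K27Me3 and H3K9Me2 values were at repeated promoters. The region at chromosome 4, 48994633 to 48997333, was highest for both, with 3.25 ± 0.66 for H3K27Me3 and 3.06 ± 0.90 for H3K9Me2 (SD over 20 probes), and all 20 of its probes match the genome more than once. Of the 10 highest regions, 9 for H3K27Me3 and 10 for H3K9Me2 consist mostly of such probes, so their signal cannot be assigned to 1 copy. The other H3K27Me3 region was at chromosome 1, 199446192 to 199448892 (2.41 ± 1.02, 27 probes, 13 of them with more than 1 match). Next for H3K27Me3 were chromosome 6, 31025337 to 31028037 (2.82), chromosome 1, 12868112 to 12870812 (2.79), chromosome 7, 97396198 to 97398898 (2.65) and chromosome 8, 7106507 to 7109207 (2.55). Next for H3K9Me2 were chromosome 19, 61052998 to 61055698 (2.67), chromosome 1, 146491972 to 146494672 (2.43), chromosome 8, 86762020 to 86764720 (2.38) and chromosome 6, 31025337 to 31028037 (2.31).

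H3K4Me3 and H3K27Me3 were both high at 2 named promoters without repeated probes. At chromosome 1, 196150939 to 196153639, H3K4Me3 was 2.27 ± 1.05 and H3K27Me3 was 1.05 ± 0.86 (SD over 21 probes), with H3K9Me2 at 0.05. At chromosome 14, 41144889 to 41147589, they were 2.26 ± 1.33 and 0.93 ± 0.82 (SD over 24 probes), with H3K9Me2 at 0.18. The other 3 of the 5 highest sums, at chromosome 7, 97396198, chromosome 6, 31025337, and chromosome 3, 125192389, consist mostly of probes with more than 1 match.

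With each array's own control and median centring, H3K27Me3 formed blocks of neighbouring promoters. The longest run held 23 enriched regions in a row over 560 kb at chromosome 12, 50971066 to 51531245. The median H3K27Me3 value there was 1.32, the median H3K4Me3 value was -0.20, none of the 23 regions was enriched for H3K4Me3, and none consists mostly of probes with more than 1 match. A run of 22 lay at chromosome 1, 150563803 to 151067072, with a median of 0.96, and 1 of 13 at chromosome 1, 151145462 to 151499323, with 1.06. A run of 13 at chromosome 9, 124279526 to 124591532, had a median of 0.92. Of the 8 H3K27Me3 runs listed as longest, 4 consist mostly of regions of repeated probes, among them a run of 17 at chromosome 17, 36403411 to 36727673, with 11 such regions. In all, 313 H3K27Me3 regions (13.3%) stood in runs of 5 or more, against a highest value of 21 in 1000 shuffles. Without regions made mostly of probes with more than 1 match, a choice made after the data were seen, the number was 223 against at most 18. For H3K9Me2 it was 116 against at most 30, and 46 against at most 17 without such regions, which make up most of 6 of the 8 runs listed as longest. The longest H3K9Me2 run, 12 regions at chromosome 1, 246123311 to 246505939, had no region enriched for H3K27Me3 and none of repeated probes. In the next, 11 regions at chromosome 19, 47790390 to 48467720, all 11 were enriched for H3K27Me3 and 10 were of repeated probes. A run of 7 at chromosome 1, 40713688 to 41102805, lies in the stretch of raised control signal. For H3K4Me3 the number in runs was 2040 against at most 1677, and its longest run of 15 was below the 31 that shuffling reached. The 20 LSD1 and 35 JHDM1A regions in such runs did not exceed the 20 and 37 that shuffling reached, and the other proteins had no run of 5, where shuffling reached at most 11 regions.

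**Figure D3:**
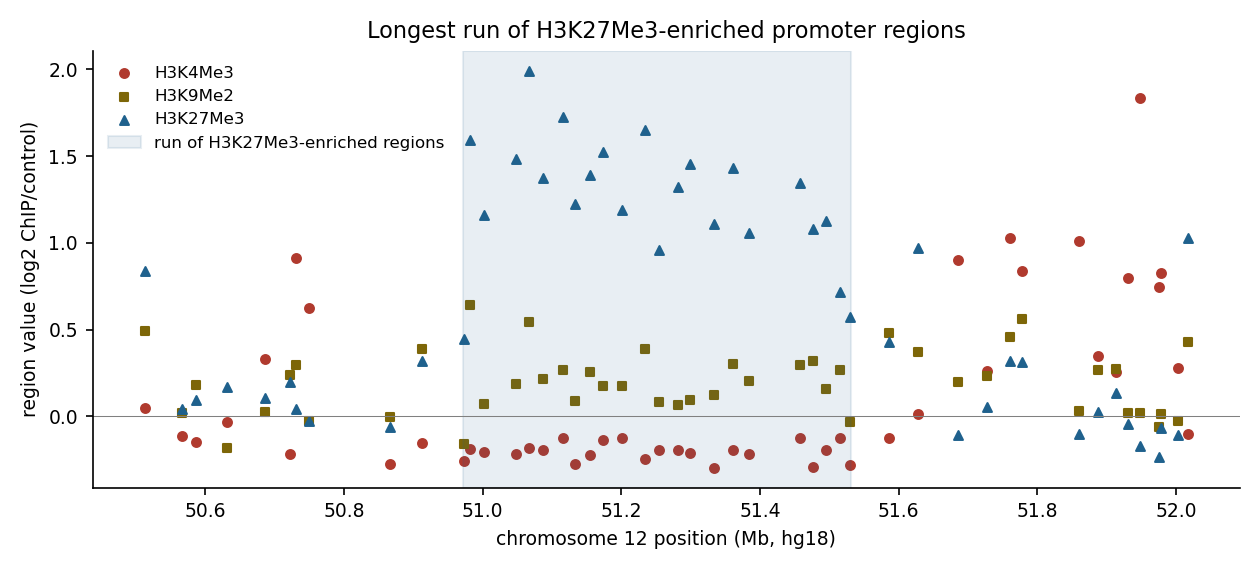
Points give the region value (vertical axis, mean log2 precipitate over control) of the 3 histone marks for each promoter region along chromosome 12 (horizontal axis, Mb in hg18). In the shaded run of 23 regions H3K27Me3 lies between 0.45 and 1.99, with a median of -0.20 for H3K4Me3.

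The third question was how high each mark stood in the regions of the proteins. Among the demethylases, JARIDIA acts on trimethylated lysine 4, whereas LSD1 acts only on lower methylation states of that lysine. JARIDIA regions overlapped H3K4Me3 regions. Of its 419 regions, 317 (75.7%) were enriched for H3K4Me3 against 228.2 for independent lists (ratio 1.39). The ratio was 1.38 after trend removal and 4.13 among the 1000 highest regions of each. With normexp JARIDIA had 1 region and with mode centring 0, so no ratio could be given there. The median H3K4Me3 value was 0.88 in JARIDIA regions (quartiles 0.11 and 1.47) against 0.21 in all regions (quartiles -0.19 and 0.70), a difference of 0.68 that was 0.27 with the mean control of all arrays. In LSD1 regions the median H3K4Me3 value was 0.25, with 1409 shared regions against 1376.3 (ratio 1.02). The 45 LSD1 regions called after trend removal, all 45 among the 2527, had a median 0.28 above all regions, and the 26 called with normexp had 0.48. H3K9Me2 differed little in regions of LSD1 (median 0.12), JHDM2A (0.13) and JHDM3A (0.14) against 0.04 in all regions, each with a ratio of shared regions between 1.93 and 2.13. With centring on the mode, which called 17602 LSD1 regions, the ratio for LSD1 was 1.01. For H3K27Me3 the median was -0.05 over all regions and lay between -0.10 in JARIDIA regions and 0.01 in JHDM1A regions among the 6 proteins with over 300 enriched regions. It was 0.18 in the 5 SNF2H regions and 0.10 in the BRG1 region.

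Promoters were also put into 10 groups of equal size by their H3K4Me3 value. The lowest group had the lowest median for all 11 antibodies, which for H3K4Me3 follows from the sorting. It was -0.43 for SNF2H, -0.41 for BRG1, -0.26 for LSD1 and -0.25 for H3K27Me3. The median JARIDIA value was -0.48 there, -0.05 in the third group and 0.31 in the highest. JHDM2A went from -0.16 to 0.18 and JHDM3A from -0.04 to 0.22, but neither in a steady course, since JHDM3A stood at 0.14 in the third group from below and at -0.02 in the fifth. The JHDM2A array has the same slide as the H3K4Me3 array that set the groups. SIN3A stood at 0.16 in the fourth group and at 0.02 in the highest. H3K27Me3 stood at 0.08 in the fourth group and at -0.12 in the highest.

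Region values of all 55 pairs of antibodies were correlated across regions. The H3K4Me3 values went with those of JARIDIA (Spearman 0.35, Pearson 0.36) and BRG1 (0.34 and 0.30), and hardly with those of H3K27Me3 (-0.08 and -0.16) or H3K9Me2 (-0.05 and -0.07). By groups of H3K4Me3 value the BRG1 median rose only at the low end, from -0.41 in the lowest group to -0.07 in the third. From the fourth to the highest group it stood between -0.01 and 0.02. The BRG1 pair was not recomputed under the alternatives. The strongest pairs were H3K9Me2 with H3K27Me3 (0.62 and 0.51), SNF2H with BRG1 (0.59 and 0.61) and H3K9Me2 with SNF2H (0.54 and 0.55). In the same order their Spearman correlations were 0.46, 0.42 and 0.00 after trend removal, and 0.38, 0.43 and 0.08 with normexp. With the mean control of all arrays they were 0.51, 0.68 and 0.11. All 28 pairs of proteins lay above 0, from 0.07 to 0.59. Whether arrays shared a control preparation is not stated. Unchanged precipitates, each the mean of all controls plus independent noise, were therefore simulated against the measured controls. This gave a Spearman correlation of 0.37 for H3K9Me2 with H3K27Me3 (covariance 0.038 against 0.045 observed), 0.20 for SNF2H with BRG1 (0.016 against 0.043), -0.03 for H3K9Me2 with SNF2H (-0.003 against 0.036), -0.09 for H3K4Me3 with JARIDIA (-0.030 against 0.109) and 0.20 for H3K4Me3 with H3K27Me3 (0.044 against -0.033). For the first 2 of these pairs part of the correlation may come from the controls. For H3K4Me3 with JARIDIA, H3K9Me2 with SNF2H and H3K4Me3 with H3K27Me3 the simulated value had the opposite sign to the observed one. All simulated pairs within the histone arrays or within the protein arrays lay above 0, and those between these sets below 0. Controls correlated at only 0.44 to 0.58 between the sets. The simulated sign thus went with the set, so an opposite sign does not tell against the controls as a source. The simulation was not fitted to the trend of the measured ratios on control signal, so it cannot exclude that trend. The correlation of H3K9Me2 with SNF2H was 0.00 once the trend was removed.

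**Figure D4:**
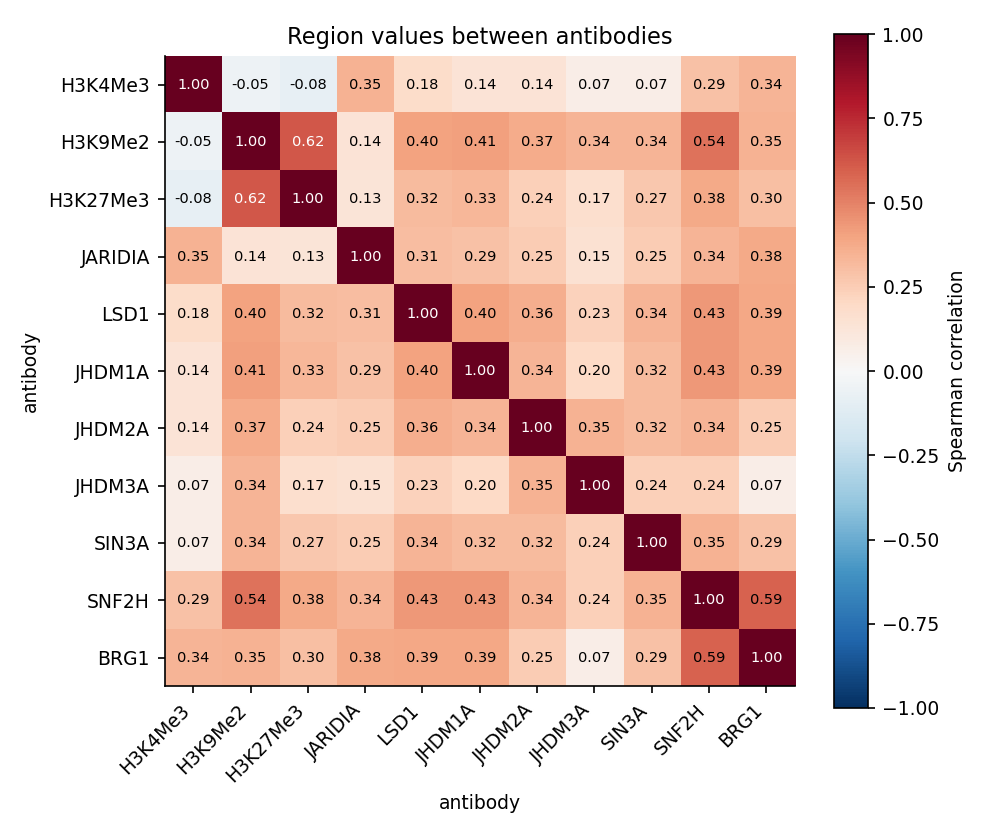
Each cell gives the Spearman correlation of region values between 2 antibodies (rows and columns) over 17973 regions, with 1 array per antibody; red is positive and blue negative. H3K9Me2 with H3K27Me3 is the highest pair at 0.62 and H3K4Me3 with H3K27Me3 the lowest at -0.08.

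The proteins shared more regions with each other than independent lists would. Over the 15 pairs among JARIDIA, LSD1, JHDM1A, JHDM2A, JHDM3A and SIN3A the ratio ran from 1.63 to 3.79 with a median of 2.14. JHDM2A and JHDM3A shared 116 regions against 30.6 (ratio 3.79), JHDM2A and SIN3A 53 against 15.1 (3.52), and JARIDIA and JHDM2A 26 against 7.7 (3.39). With the mean control of all arrays these ratios were 2.15, 1.72 and 1.68. After trend removal and with normexp the JHDM2A list of 20 regions was too short for a ratio in any of these pairs. The other pairs among the proteins were not recomputed. After trend removal the longest lists were JHDM3A with 285 and JARIDIA with 276, and with normexp no protein had more than 26. The sharing was therefore not checked in either setting. No region was enriched for all 6, 13 were for 5, and 81 were for at least 4. These 6 arrays carry a mark of re-use in the track names, and simulated unchanged precipitates gave a Spearman correlation of 0.09 for JHDM2A with JHDM3A against 0.35 observed (covariance 0.014 against 0.050).

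The highest JARIDIA region was at chromosome 22, 40192874 to 40196854 (2.88 ± 1.37, SD over 31 probes), followed by chromosome 11, 19179677 to 19182377 (2.84 ± 0.98, 16 probes). For JHDM2A it was chromosome 1, 181114842 to 181117542 (3.58 ± 0.66, 19 probes), followed among regions with unique probes by chromosome 22, 37214412 to 37217112 (2.47). Chromosome 17, 45218869 to 45221569, had 2.96 for SIN3A, chromosome 1, 45861816 to 45864516, had 2.27 for LSD1, chromosome 2, 48659066 to 48661766, had 2.19 for JHDM1A and chromosome 19, 18204516 to 18207216, had 1.89 for JHDM3A. The region at chromosome 19, 61052998 to 61055698, was among the 5 highest of LSD1 (3.05), JHDM1A (3.52), JHDM2A (2.49) and JHDM3A (2.38), and 18 of its 27 probes have more than 1 match. The region at chromosome 10, 683687 to 686387, was highest for SIN3A (3.59) and JHDM3A (2.83), with 17 of 27 such probes. Among the 5 enriched SNF2H regions the highest was at chromosome 17, 45704631 to 45707331 (0.74 ± 0.88, 23 probes). The enriched BRG1 region was at chromosome 19, 7491311 to 7494011 (0.75 ± 0.94, 24 probes). Regions not called enriched reached 1.11 for SNF2H and 1.48 for BRG1. In the enriched region with the highest mean, the median over probes was 0.42 for SNF2H and 0.50 for BRG1.

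Within the promoter, H3K4Me3 and JARIDIA differed in shape. Over the 15989 regions of 2700 bp, the mean H3K4Me3 ratio was 0.51 in the middle (1200 to 1400 bp) and 0.08 at 300 to 500 bp from either end, with minima of 0.00 at 500 to 600 bp and 0.02 at 2100 to 2300 bp. It rose again at the edges, to 0.30 at 0 to 100 bp and 0.29 at 2600 to 2700 bp (0.73 and 0.71 in H3K4Me3-enriched regions). JARIDIA averaged -0.08 in the middle and 0.06 near the ends, and BRG1 -0.17 and -0.03. JHDM3A followed H3K4Me3, with 0.16 in the middle and 0.07 near the ends. H3K27Me3 was flat, at 0.06 in both places (0.13 in the middle and 0.09 near the ends after trend removal). In H3K4Me3-enriched regions, which were selected for a high H3K4Me3 ratio, H3K4Me3 had 1.13 in the middle against 0.34 near the ends, and JARIDIA had 0.02 against 0.20. Strands were not used, so each end may be the upstream or the downstream one. The mean profile mixes regions without regard to strand, and its shape may differ from that of a profile aligned by strand.

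**Figure D5:**
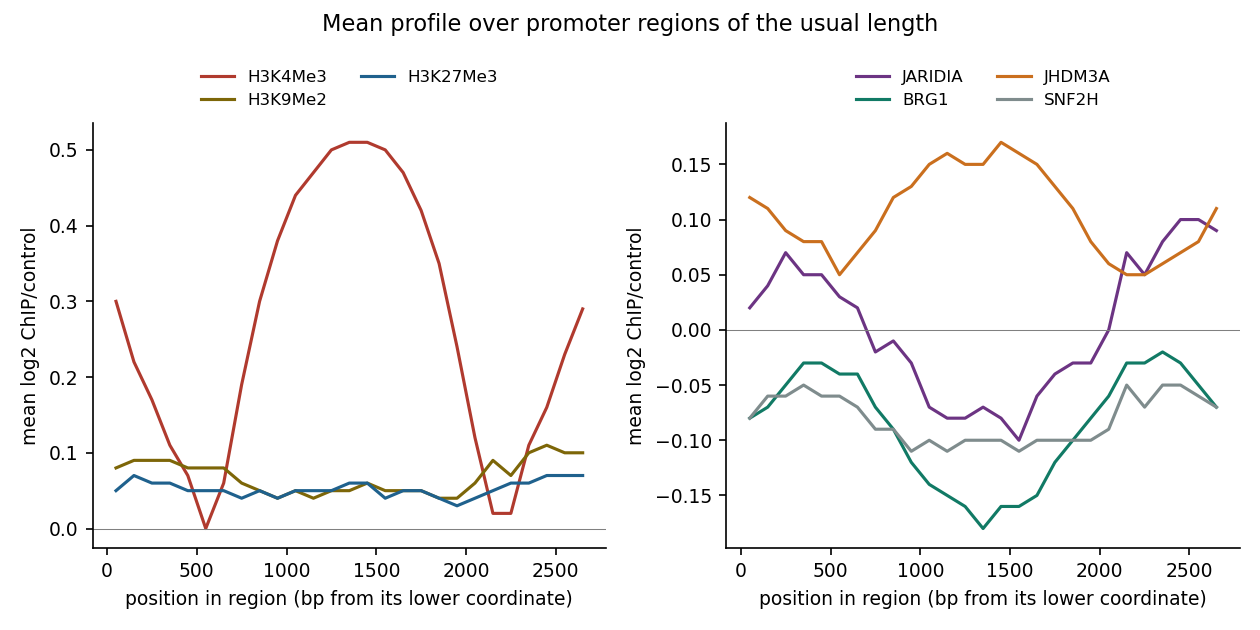
Lines give the mean log2 ratio of precipitate over control (vertical axis) of all probes in bins of 100 bp along 15989 promoter regions (horizontal axis, bp from the lower coordinate), for the 3 marks on the left and for 4 proteins on the right; the vertical scales differ. H3K4Me3 peaks in the middle at 0.51 and has minima of 0.00 and 0.02 on either side before it rises to 0.30 and 0.29 at the edges, whereas JARIDIA and BRG1 are lowest in the middle.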

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

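The tests of re-use of slides and of repeated probes in the chromosome 1 stretch, and leaving out probes with more than 1 match, were chosen after the results were seen. The BRG1 track, which the comparisons do not use because it comes from another slide, carried a signal that followed the SNF2H scanner ratios (Spearman 0.65 over regions) more closely than the BRG1 scanner ratios (0.49). With the H3K9Me2 scanner ratios it was 0.51.

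The first pattern is the correlation of 0.62 between H3K9Me2 and H3K27Me3. Repeated probes do not account for it, since it was 0.61 over the 13919 regions with no such probe. Probe brightness stays open, since both marks were read against a control near background and rose with the mean control signal of the protein arrays (0.76 and 0.53, against 0.11 for H3K4Me3). Given that signal, the partial correlation was 0.39, between the levels set for and against, so brightness and a real overlap of the marks cannot be told apart. The control channels stay open too, since unchanged precipitates simulated against them gave 0.37 (covariance 0.038 against 0.045 observed).

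The second pattern is the overlap of H3K9Me2 regions with those of the 6 proteins on re-used slides (median ratio 2.01). JHDM1A has the same slide as H3K9Me2 and a mark of re-use in its track name, so H3K9Me2 is taken to have come first. The order is not stated. Its ratio of 2.09 with H3K9Me2 lay within the 1.12 to 2.13 of the other 5 proteins. Under that order this argues only against an added effect of H3K9Me2 carried over on its own slide. The other 5 proteins are on re-used slides too, JHDM2A on that of H3K4Me3 and JHDM3A on that of H3K27Me3. H3K27Me3 itself overlaps H3K9Me2 (ratio 2.08), and the first antibodies on the JARIDIA, LSD1 and SIN3A slides are not known. Carry-over in general therefore stays open. Leaving out repeated probes gave a median ratio of 2.28, which argues against them. The trend of the ratio on control signal stays open, since its removal left 1.73 over 4 proteins but only 1 of the 6 proteins retained at least 50% of its number of regions. A real overlap is untested.

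The third pattern is the raised control signal at chromosome 1, 39929176 to 41102805. Of the 22 regions on the array within it, 1 (4.5%) consists mostly of repeated probes, and the signal of the 21 used here was taken over probes with 1 match, which argues against repeated probes as the cause. The running median of 1.58 compares with 0.97 in the next stretch, at 43605786 on the same chromosome, and 0.87 on any other. That gap met the level set beforehand against bright probes that happen to lie together. However, the stretch was chosen as the highest on this same measure, and the signal stayed raised between it and 43605786. No measure of probe brightness apart from this signal was used, so bright probes are not excluded. A gain of copies in this cell line is a candidate explanation. The stretch was chosen on the 8 protein arrays, so only the histone arrays bear on it, and there as few as 66.7% of the regions lay above the chromosome median on an array, between the levels set for and against, which left it open.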

How the results depend on the processing

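No test across arrays was possible, so a count is called stable within 1.5 times and a correlation or difference within 0.1. Of the alternative counts of enriched regions 55 stayed and 55 moved. Of correlations 39 stayed and 10 moved, and of overlap ratios 33 stayed, 8 moved and 1 crossed 1. Of differences in a mark, counted together with the same-slide correlation, 55 stayed and 3 moved. The H3K9Me2 and H3K27Me3 differences were below 0.1 in size at the outset, so for them staying says little. Under the mean control the H3K9Me2 difference went from 0.09 to 0.01 in both JHDM2A and JHDM3A regions. That of H3K27Me3 went from 0.05 to -0.01 in LSD1 regions and from -0.05 to -0.07 in JARIDIA regions. Of counts in runs 2 stayed and 1 moved, under the only alternative tried for them, leaving out regions mostly of repeated probes. Runs were not recomputed under the other settings. Of the highest enriched regions, mean against median over probes, 1 stayed and 10 moved. H3K4Me3 stayed within 1.5 times in all settings but the mean control of all arrays. The causes were not tested. No paired analysis was possible because each antibody has 1 array. The planned comparisons of gene lists were not run, for want of gene names. Overlap ratios with under 5 shared regions expected, and mark differences over fewer than 10 regions, were left out. Signal over background limits the histone controls and, at the noise of the protein arrays, weak enrichment.

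Enriched counts under the mean control were 6127 for H3K4Me3, 4 for H3K9Me2, 3609 for JARIDIA, 6300 for LSD1, 4840 for JHDM1A, 2310 for JHDM2A, 3093 for JHDM3A, 4559 for SIN3A and 11 for BRG1. Mode centring gave 12278 for H3K9Me2, 17602 for LSD1, 15159 for JHDM1A, 521 for JHDM2A, 3532 for JHDM3A, 87 for SIN3A, and 0 for JARIDIA, SNF2H and BRG1. Normexp gave 3592 for H3K27Me3, 1 for JARIDIA, 26 for LSD1, 20 for JHDM2A, 1 for JHDM3A, 8 for SIN3A, and 0 for JHDM1A, SNF2H and BRG1. Trend removal gave 3634 for H3K27Me3, 276 for JARIDIA, 45 for LSD1, 20 for JHDM2A, 285 for JHDM3A, 38 for SIN3A, and 0 for JHDM1A, SNF2H and BRG1. A lower tail of 1% gave 118 for JARIDIA, 838 for LSD1, 950 for JHDM1A, 69 for JHDM2A, 14 for JHDM3A and 243 for SIN3A. Windows of 9 probes gave 1120 for H3K9Me2, 144 for JARIDIA, 1409 for LSD1, 369 for SIN3A, 2 for SNF2H and 0 for BRG1, and windows of 3 gave 3777 for H3K9Me2 and 0 for BRG1. Without the dimmest probes H3K9Me2 had 4242 and BRG1 had 2. Without repeated probes, added after the data were seen, H3K9Me2 had 1569 and SNF2H had 3. Without regions mostly of such probes, also added later, 46 H3K9Me2 regions stood in runs of 5 or more. The authors' track gave 3 for BRG1.

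The correlation of H3K9Me2 with H3K27Me3 was 0.51 under the mean control, 0.38 under normexp and 0.46 after trend removal, and that of H3K9Me2 with SNF2H was 0.11, 0.08 and 0 in the same order. SNF2H with BRG1 was 0.43 under normexp and 0.42 after trend removal. With the highest running mean as region value, H3K9Me2 with SNF2H was 0.40 and SNF2H with BRG1 was 0.38. Among the 1000 highest regions the overlap ratio of H3K4Me3 with H3K9Me2 crossed 1, to 1.46, while H3K9Me2 with H3K27Me3 had 3.81 and H3K4Me3 with JARIDIA had 4.13. Under the mean control JARIDIA with JHDM2A had 1.68, JHDM2A with JHDM3A 2.15 and JHDM2A with SIN3A 1.72. Mode centring gave 1.30 for H3K9Me2 with H3K27Me3, 2.49 for JHDM2A with JHDM3A and 1.01 for H3K9Me2 with LSD1. In the enriched region with the highest mean, the median over probes was 3.34 for H3K4Me3 and H3K9Me2, 3.08 for JARIDIA, 4.29 for LSD1 and 3.99 for JHDM1A. It was 3.73 for JHDM2A, 3.93 for JHDM3A, 4.81 for SIN3A, 0.42 for SNF2H and 0.50 for BRG1. The H3K4Me3 difference was 0.27 in JARIDIA regions under the mean control, and in LSD1 regions 0.48 under normexp and 0.28 after trend removal. Pairs on the same slide had a mean correlation of 0.24, and the 6 pairs of the same antibodies on different slides 0.25.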

Other observations

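Fewer promoters of the X chromosome were enriched for each of the 3 marks than on the array as a whole. Of its 736 regions, 45.1% were enriched for H3K4Me3 against 54.5% of all regions, 8.2% for H3K9Me2 against 13.9% and 6.8% for H3K27Me3 against 13.1%. The share was also lower for LSD1 (12.0% against 14.1%), JHDM1A (14.1% against 15.8%), JHDM3A (5.8% against 9.3%) and SIN3A (3.1% against 4.6%), was 2.3% in both for JARIDIA and was 1.9% against 1.8% for JHDM2A. Of the 22 autosomes, 4 lay below the X chromosome for LSD1, 5 for JHDM1A, 3 for SIN3A and 0 for JHDM3A. Single autosomes also lay lower for H3K4Me3 (chromosome 21, 41.2%) and H3K9Me2 (chromosome 4, 6.5%), but none of the 22 for H3K27Me3, where the lowest had 9.7%. These values were not tested.

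The chromosome 1 stretch with raised control also had raised ratios on all 11 arrays. The median region value there was 1.05 for JARIDIA, 0.92 for LSD1 and 0.83 for JHDM1A, against 0.03, 0.12 and 0.13 over all regions, and 0.56, 0.31 and 0.34 with normexp. Of its 21 regions 19 were enriched for H3K4Me3, 14 for H3K9Me2, 10 for JHDM1A, 5 each for H3K27Me3 and JHDM3A, 4 for LSD1, 2 for JARIDIA and 0 for JHDM2A, SIN3A, SNF2H and BRG1.

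The lowest control signal lay on chromosome 9, from 21196642 to 21793134, over 12 regions. On the 8 protein arrays 15.0% of its probes exceeded the 95th percentile of random-sequence probes in the control channel and 19.5% in the precipitate channel, against 49.8% and 49.5% over all regions. At 21471812 to 21474512 none of the 19 probes did so in either channel. The running median of control signal was -0.56 there and -0.47 in the next lowest stretch elsewhere.

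The control channels of the histone arrays stood apart. Probe signals correlated at 0.84 to 0.97 among the 3 histone arrays, at 0.83 to 0.96 among the 6 re-used arrays and at 0.94 between SNF2H and BRG1, and at 0.71 to 0.85 between the re-used arrays and SNF2H or BRG1. Between the histone arrays and the others they correlated at 0.44 to 0.58.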
